A study of Homo sapiens with 4 samples.

How the data were processed

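Per the submitters' processing notes, reads were aligned with STAR 2.6.0c, quantified per gene with RSEM 1.3.0 and compared with DESeq2 1.18.1 on hg38; the sources used here do not give the annotation release or the counting strand. The signal values, 1 per gene and library, are normalized counts that the authors divided by a size factor per library, as deposited. The log2 values are the fold changes and standard errors of the authors' own comparison, as deposited. The score values are the test statistics of that comparison, as deposited by the authors. The p-values and adjusted p-values are those of the same comparison, as deposited by the authors. These deposited statistics served here only to count and compare the authors' calls. The fold changes, standard errors and p-values in the results below come from limma, unless another test is named. The columns beginning with ONG were taken as No glucose because the table names only these 2 groups and the other 2 columns are named CTRL.

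Dividing each library by its smallest step returned values within 0.01 of a whole read for 100% of values above 0, and the size factors obtained (2.91, 0.748, 0.660 and 0.713 for CTRL_7, CTRL_8, ONG_9 and ONG_10) equal those of the median-of-ratios method. The table held 60868 entries for 60609 gene identifiers, of which 58502 are in GENCODE 29, the source of biotypes, coordinates and lengths here. Symbols were deposited for 26411 identifiers and came from separate reference gene names alone for 16493. The design, the gene lists, the rule for named genes and most other settings tried were fixed before the data were examined. That design gave edgeR as the test for counts and limma for a table without counts; the table holds normalized counts, so limma was used, and edgeR on the recovered reads became an alternative.

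Genes with a mean normalized count of at least 1 were tested with limma 3.58.1 (trend) in R 4.3.3 on log2(normalized count + 1), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with adjustment over 34 lists, and again with an estimated correlation and with fry. With 2 libraries per group, camera with an estimated correlation has little power, so a miss there does not argue against a list. Each list was also counted with adjustment over its own members alone. Alternatives used edgeR 4.0.16, DESeq2 1.42.0, limma-voom, other scalings, filters and pseudocounts, and left out each library in turn.

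Named genes were all tested AMPK pathway kinases, 18 genes fixed beforehand, and the 8 genes with the largest change in each direction among called genes with an average log2 CPM of at least 1, groups that did not overlap and a symbol that is not a clone, noncoding or pseudogene-like name. To these the rule added, for each list, up to 3 called members in the direction most took and 1 in the other. Some genes that the rule names are not reported here. The lists were AMPK pathway kinases, ATF4 stress response, ER chaperones, glycolysis, MondoA/ChREBP, hexosamine, pentose phosphate, serine and folate, TCA cycle, nuclear OXPHOS, mitochondrial mRNAs, fatty acid oxidation, cholesterol synthesis, fatty acid synthesis, autophagy and lysosome, p53 targets, BCL2 family, DNA replication, mitosis, histones, ribosome biogenesis and MYC targets, cytosolic ribosomal proteins, hypoxia, NRF2, interferon, NF-kB, immediate early genes, T-lineage, NOTCH and T-ALL oncogenes, acetylation and BET, methylation enzymes, and B cell, myeloid, adherent cell and erythroid markers.

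On simulated libraries with 50 changed genes at each fold, limma called 38 genes changed 1.5-fold, 50 changed 2-fold, 50 changed 4-fold and 46 changed 0.5-fold, with 11 false calls among 195. camera and fry called the simulated changed list and 0 of 34 random lists. Genes were drawn independently there and few were changed, so these calls do not check the preset correlation or data with widespread change. The changed genes were chosen from those with a mean normalized count of at least 50, so recovery of lower genes was not checked.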

Results

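CCRF-CEM is an established line of human T cell acute lymphoblastic leukaemia, here in a derivative that carries an HA-tagged AMPK alpha 2 subunit. The comparison asks how gene expression in these leukaemia cells differs after 24 hours in medium without glucose, a metabolic stress, from that in control medium. Total RNA was sequenced in 2 control libraries (Ctrl) and 2 libraries from glucose-deprived cells (No glucose). The reads recovered for genes numbered 96698709 and 24513840 in the control libraries, CTRL_7 and CTRL_8. They numbered 19035535 and 20081266 in the No glucose libraries, ONG_9 and ONG_10. Pearson's r of log2 values across 10858 genes was 0.999 within Ctrl, 0.994 within No glucose, and 0.947 to 0.953 between groups. Genes are not independent replicates in these correlations. The recovered reads of the 2 libraries of a group were also compared, over genes with at least 20 reads. The chi-square per degree of freedom was 1.81 in Ctrl and 5.72 in No glucose, so the No glucose pair differed more. limma fits 1 spread per gene to both groups, although the spreads were unequal. The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

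Without glucose, HSPA6, a stress-inducible HSP70 chaperone, had the largest rise. It had 0 reads in both control libraries and 2563 ± 117 normalized counts without glucose (SD, n = 2), at least 3126-fold higher than the floor of 3 reads over the control group, 0.820 normalized counts. The orphan nuclear receptors NR4A3 and NR4A2 rose by 4.93 ± 0.15 and 4.43 ± 0.19 on the log2 scale (SE). NR4A3 went from 30.9 ± 5.86 to 966 ± 33.4 normalized counts (SD, n = 2). SH3RF2, ATP6V0A4 (a proton pump subunit), the pseudokinase TRIB1 and the G protein regulator RGS1 were also among the 8 largest rises among genes with an average log2 CPM of at least 1, with log2 fold changes from 3.94 to 5.04. Among genes at that level the deepest fall was that of TXNIP, a glucose-induced inhibitor of glucose uptake, from 13431 ± 90.3 to 1480 ± 114 normalized counts, a log2 fold change of -3.18 ± 0.06 (SE, limma with Benjamini-Hochberg adjustment, adjusted p = 3.4e-10). Other deep falls were those of the surrogate light chain gene IGLL1 (-2.99), SCD (-2.74), BATF3 (-2.73), C6orf223 (-2.70), CAMKV (-2.61) and CHAC1 (-2.59).

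Of 27486 genes tested with limma, 9643 changed at an adjusted p under 0.05, 3948 of them higher and 5695 lower without glucose. At an absolute log2 fold change of at least 1, 1545 genes were higher and 1231 lower. Of 10656 protein-coding genes with a mean normalized count of at least 50, 5025 were lower and 2013 higher, with a median log2 fold change of -0.20. The set test camera compared each list with all other tested genes. Its p-values therefore do not test a list of coding genes against coding genes alone. Fold changes are on the log2(normalized count + 1) scale, which understates the change of low genes. Among all genes tested, 66.8% had both No glucose libraries on the same side of both control libraries, against 33.3% given by chance. Scaling to library totals moved the median log2 fold change from 0.04 to 0.24 and the share of higher calls from 40.9% to 61.5%, with 6103 genes higher and 3821 lower, so small changes of either sign depend on the scaling. The count was 5345 without CTRL_7 and 6101 without CTRL_8, and the authors' deposited table has 7194 genes at an adjusted p under 0.05, of which 7191 were called here in the same direction.

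**Figure D1:**
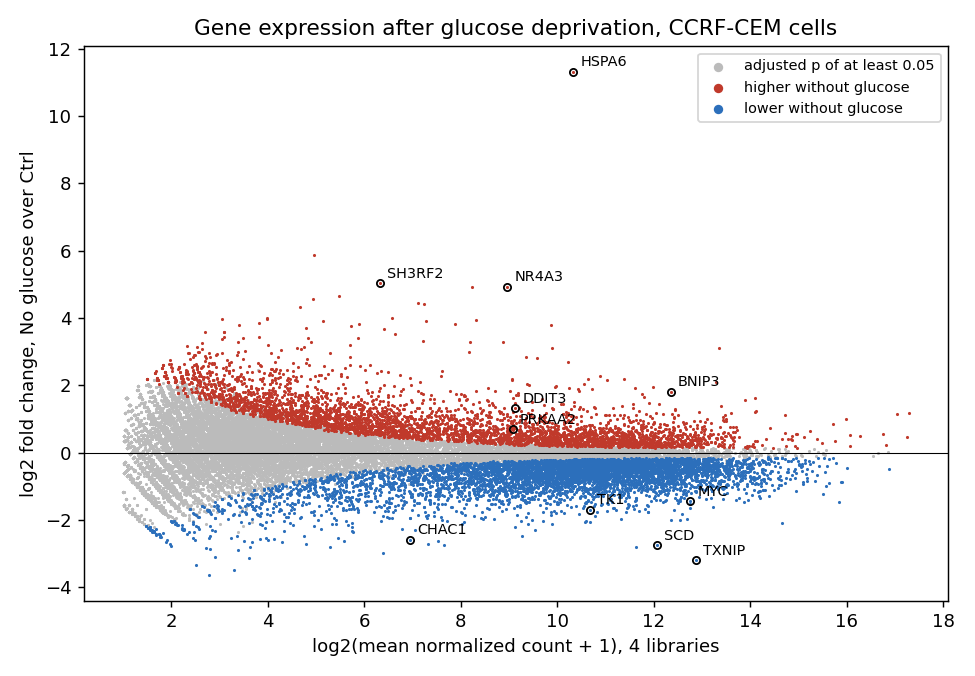
Log2 fold change, No glucose over Ctrl, against log2 of the mean normalized count plus 1 for the 27486 genes tested, 1 point per gene. Red points are the 3948 genes higher and blue points the 5695 genes lower at an adjusted p under 0.05; circles mark named genes, with HSPA6 at the top (11.32, fitted against 0 reads in Ctrl) and TXNIP at -3.18.

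TXNIP, ARRDC4 and KLF10, whose transcription follows intracellular glucose, fell, while hypoxia-type genes and several glucose-handling genes rose. Of the MondoA/ChREBP list, the glucose-sensing transcription factors and their targets, 4 of 6 tested members fell and 2 rose, the same counts when adjusted over the list alone. ARRDC4, an arrestin relative regulated like TXNIP, fell from 267 ± 13.9 to 78.0 ± 0.883 normalized counts (log2 fold change -1.76 ± 0.13, SE), and KLF10 changed by -1.06 ± 0.08. The set itself missed the threshold in camera, limma's competitive set test, at adjusted p = 0.060, and passed it under 12 of 21 alternatives, among them those without CTRL_7 (0.044) and without CTRL_8 (0.012), but not without ONG_9 (0.081) or ONG_10 (0.13). The count of risen members was 1 without CTRL_7, CTRL_8 or ONG_10. Of 24 glycolysis genes, 10 rose and 7 fell, as they did adjusted over the list alone. The glucose transporter SLC2A3 (1.31 ± 0.08), the fructose 2,6-bisphosphate producing enzyme PFKFB3 (1.07 ± 0.07), the pyruvate dehydrogenase kinase PDK1 (0.77 ± 0.06), the hexokinase HK2 (0.66 ± 0.06) and LDHA (0.52 ± 0.05) were among the rises in log2 fold change. The muscle-type phosphofructokinase PFKM changed by -1.09 ± 0.07. SLC2A1, the widely expressed glucose transporter, rose by 0.32 ± 0.06, with adjusted p = 0.0015, and by 0.35 and 0.29 with adjusted p = 0.067 and 0.097 without CTRL_7 and without CTRL_8. Glycolysis as a set had adjusted p = 0.12 and passed under 8 of 21 alternatives. With scaling to library totals 14 rose and 4 fell (adjusted p = 0.0093), after a GC and length correction 16 rose and 5 fell (adjusted p = 0.00051), without ONG_9 the adjusted p was 0.018, and without CTRL_7 3 members fell.

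Of 20 hypoxia response genes 13 rose and 2 fell, in both adjustments (camera adjusted p = 2.1e-07; adjusted p = 0.17 with an estimated correlation). The vasoactive peptide gene ADM went from 2.37 ± 0.434 to 84.0 ± 18.1 normalized counts (SD, n = 2), the repressor BHLHE40 from 192 ± 5.08 to 877 ± 1.65, and the mitophagy receptor BNIP3 from 2311 ± 0.753 to 8129 ± 289. No member fell without CTRL_7 or without CTRL_8. The hexosamine list is wider than the pathway that makes the sugar donor for protein O-GlcNAc. Of its 13 tested members 6 fell and 3 rose, in both adjustments, with camera adjusted p = 0.12 for the set, which passed under 2 of 21 alternatives. UAP1 (-1.24 ± 0.08), GNPDA1 (-1.04 ± 0.07) and NANS (-0.95 ± 0.08) fell, and the O-GlcNAc transferase OGT was higher by 0.68 ± 0.05 (log2, SE).

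Sterol and fatty acid synthesis fell almost throughout. Of 23 cholesterol synthesis genes 21 fell and none rose, in both adjustments, with a median log2 fold change of -1.29 (camera adjusted p = 5.5e-17; adjusted p = 0.17 with an estimated correlation). With scaling to library totals 19 fell and 1 rose. DHCR7, a reductase of the pathway, went from 1345 ± 91.4 to 328 ± 52.1 normalized counts (SD, n = 2), and the lanosterol synthase LSS from 656 ± 51.7 to 169 ± 30.9. Of 15 fatty acid synthesis genes 14 fell and none rose, in both adjustments (median -1.32, adjusted p = 3.9e-11; adjusted p = 0.17 with an estimated correlation). The desaturases SCD and FADS2 went from 7403 ± 93.2 to 1104 ± 21.3 and from 9497 ± 282 to 2380 ± 130 normalized counts, and the fatty acid synthase FASN from 4191 ± 530 to 1296 ± 508.

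Genes of growth and S phase fell together. Of 42 DNA replication genes 41 fell and none rose, in both adjustments, with a median log2 fold change of -1.04 (camera adjusted p = 5.9e-28; adjusted p = 0.17 with an estimated correlation), and 40 fell and 1 rose with scaling to library totals. Thymidine kinase TK1 went from 2504 ± 117 to 777 ± 99.7 normalized counts (SD, n = 2), the flap endonuclease FEN1 from 8533 ± 29.5 to 3044 ± 22.9, and the helicase subunit gene GINS1 from 6829 ± 173 to 2492 ± 115. Of 55 histone genes 50 fell and none rose, in both adjustments (median -0.95, adjusted p = 9.5e-25; adjusted p = 0.34 with an estimated correlation), with H1-1 at -2.49 ± 0.10. Their share of all reads was 3.16% ± 0.0859 in Ctrl and 1.90% ± 0.249 without glucose (SD, n = 2), and near-identical histone genes share reads, so single members are uncertain. In the mitosis list 27 of 35 members fell and 1 rose, 28 and 1 adjusted over the list alone (median -0.35, camera adjusted p = 2.8e-09, and 0.44 with an estimated correlation). Across the alternatives the median of this list ranged from -0.42 to -0.13. AURKB (-1.12 ± 0.06), CCNA2 (-0.79 ± 0.05) and BIRC5 (-0.74 ± 0.06) fell, while the proliferation marker MKI67 went the other way, from 24323 ± 177 to 31999 ± 1319 normalized counts. Scaling to library totals left 18 mitosis genes lower and 3 higher, and 16 were lower without CTRL_7.

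The oncogenic transcription factor MYC fell from 10068 ± 225 to 3721 ± 41.4 normalized counts (SD, n = 2; log2 fold change -1.44 ± 0.05, SE, adjusted p = 1.6e-08). Of 40 ribosome biogenesis and MYC target genes, MYC among them, 38 fell and none rose, in both adjustments (median -0.90, adjusted p = 1.9e-24; adjusted p = 0.17 with an estimated correlation). NME1 (-1.98 ± 0.06), the nucleolar factor LYAR (-1.71 ± 0.06) and the spermidine synthase SRM (-1.59 ± 0.09) fell the furthest. Cytosolic ribosomal protein genes shifted less: 47 of 74 fell and 1 rose, 51 and 1 adjusted over the list alone. Their median of -0.22 was close to the -0.20 of protein-coding genes with a mean normalized count of at least 50. These medians were not matched for transcript length. The set had a camera adjusted p = 1.1e-08, and 0.17 with an estimated correlation, and RPL6 (-0.74 ± 0.05) moved the most. The balance depends on the processing, since 13 fell and 15 rose with library totals (median -0.01, adjusted p = 0.19), 32 fell and 12 rose after a GC and length correction (median -0.05), and 6 fell without CTRL_7 and 17 without CTRL_8. Their share of reads was 4.08% ± 0.0114 in Ctrl and 4.06% ± 0.0562 without glucose (SD, n = 2). In the pentose phosphate pathway 10 of 12 members fell and 1 rose, in both adjustments (adjusted p = 3.3e-05; adjusted p = 0.17 with an estimated correlation), with the transaldolase TALDO1 at -1.16 ± 0.06, PRPS2 at -1.06 ± 0.06 and H6PD, its reticulum-resident enzyme, at 0.64 ± 0.07. Serine and folate metabolism had 10 of 15 members lower and none higher, 11 and none adjusted over the list alone (adjusted p = 5.8e-06; adjusted p = 0.18 with an estimated correlation). MTHFD1 (-1.23 ± 0.05) and SHMT1 (-1.10 ± 0.07) were among its falls.

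Nuclear and mitochondrial genes of respiration moved in opposite directions. Of 74 nuclear OXPHOS genes 66 fell and 1 rose, 66 and 2 adjusted over the list alone, with a median log2 fold change of -0.68 (camera adjusted p = 1.4e-24; adjusted p = 0.17 with an estimated correlation). Across the alternatives its median ranged from -0.69 to -0.46. The set test does not match lists for transcript length, and short coding transcripts fell more than long ones. In the fifth of coding genes with the shortest transcripts the median was -0.44. The ATP synthase subunit gene ATP5MC1 went from 3449 ± 23.5 to 1097 ± 17.9 normalized counts (SD, n = 2) and the complex III gene UQCR11 from 916 ± 17.6 to 412 ± 20.7. With scaling to library totals 62 fell and 5 rose, and 3 rose without ONG_10. Of 25 genes on the TCA cycle list, which is wider than the cycle itself, 20 fell and none rose, 21 and none adjusted over the list alone (camera adjusted p = 1.9e-11, and 0.17 with an estimated correlation). The lowest on the list were IDH1 (-1.30 ± 0.08), DLAT (-1.17 ± 0.05) and FH (-1.06 ± 0.05). Of the 13 mRNAs made from mitochondrial DNA 8 rose and 1 fell, in both adjustments (median 0.46, adjusted p = 1.1e-05; adjusted p = 0.48 with an estimated correlation). MT-CO1 went from 38378 ± 456 to 68960 ± 3331 normalized counts, MT-ND4 from 3197 ± 2.41 to 5768 ± 224 and MT-ATP6 from 2270 ± 155 to 4460 ± 428. The fall was in MT-ND6, the mRNA of the other strand, at -0.36 ± 0.09, with adjusted p = 0.0066, and was not called without CTRL_7 (0.094) or without CTRL_8 (0.15). With scaling to library totals 12 of these mRNAs rose and none fell, with a median of 0.67. The mitochondrial mRNAs made up 0.430% ± 0.0123 of reads in Ctrl and 0.706% ± 0.0334 without glucose.

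Fatty acid oxidation genes fell rather than rose: 14 of 26 were lower and 2 higher, 15 and 3 adjusted over the list alone (camera adjusted p = 0.00069; adjusted p = 0.34 with an estimated correlation). The median of the list was -0.37, against -0.20 for protein-coding genes with a mean normalized count of at least 50. CPT1A, the carnitine transferase that admits fatty acids to mitochondria, went from 7923 ± 124 to 4505 ± 35.5 normalized counts (SD, n = 2), and the coactivator PPARGC1B from 738 ± 14.7 to 286 ± 2.30. PLIN2, a lipid droplet coat protein that belongs to the list as a PPAR target, was higher by 0.77 ± 0.06 (log2, SE). Without CTRL_8, 1 member was higher. The call of this list was lost under 5 of 21 alternatives, among them edgeR with library totals, at adjusted p = 0.080.

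**Figure D2:**
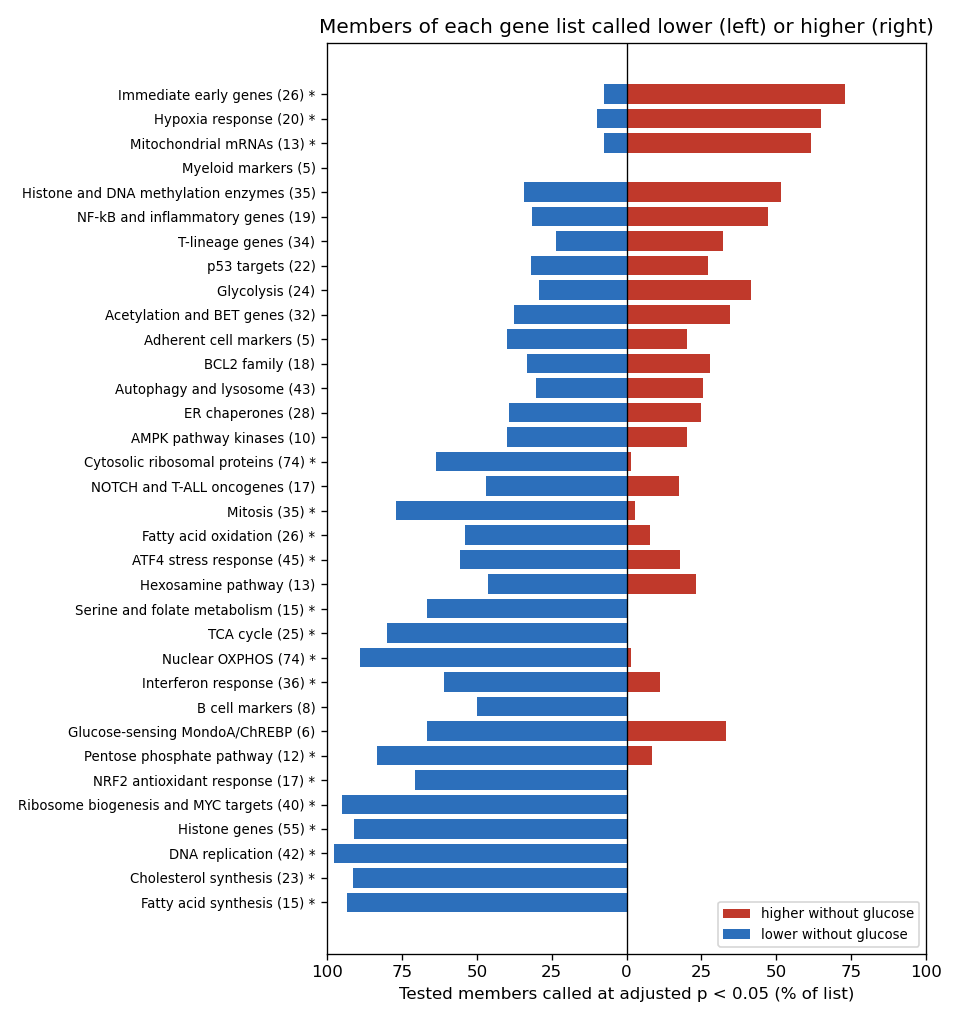
Percent of each list's tested members (number in brackets) called lower, drawn to the left in blue, or higher, drawn to the right in red, at an adjusted p under 0.05; lists are ordered by median log2 fold change and an asterisk marks the 18 of 34 lists called by camera with a preset correlation. DNA replication reaches 41 of 42 lower and immediate early genes 19 of 26 higher; with scaling to library totals the medians of the AMPK kinase, ER chaperone, autophagy, BCL2, acetylation and adherent cell lists turn from below to above 0, and cytosolic ribosomal proteins have 15 higher and 13 lower.

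Stress genes split rather than moving as a block. Of 45 ATF4 stress response genes, targets of the amino acid and unfolded protein responses, 25 fell and 8 rose, in both adjustments (camera adjusted p = 0.00039; adjusted p = 0.34 with an estimated correlation). The median of the list was -0.41, against -0.20 for protein-coding genes with a mean normalized count of at least 50. ATF4 itself went from 11863 ± 94.3 to 6823 ± 190 normalized counts (SD, n = 2), CHAC1, a glutathione-degrading enzyme, from 211 ± 4.63 to 34.3 ± 0.847, and the proline enzyme PYCR1 from 407 ± 40.6 to 141 ± 19.1. EIF4EBP1, a repressor of translation initiation, changed by -1.24 ± 0.08 (log2, SE). Against that direction PPP1R15A, a phosphatase subunit that restores translation, went from 647 ± 24.5 to 3131 ± 106, DDIT3 (CHOP) from 318 ± 30.2 to 797 ± 7.58, and the pseudokinase TRIB3 rose by 0.42 ± 0.07. ASNS was low in both groups, 20.5 ± 3.21 and 19.7 ± 2.11 normalized counts, with log2 fold change -0.05 ± 0.31 and adjusted p = 0.93, and of either sign under other scalings. Without CTRL_7, 4 ATF4 genes rose. Of 28 ER chaperone genes 7 rose and 11 fell, 8 and 12 adjusted over the list alone, with adjusted p = 0.67 for the set, whose median turned from -0.13 to 0.08 with scaling to library totals, where 12 rose and 7 fell; 5 fell without CTRL_7. The sensor kinase ERN1 (1.93 ± 0.07) and the chaperone HSPA5 (0.77 ± 0.06) rose, while SDF2L1 (-1.02 ± 0.13), SEC61B (-0.63 ± 0.09) and PDIA6 (-0.57 ± 0.05) fell.

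Immediate early genes rose: 19 of 26 were higher and 2 lower, 20 and 2 adjusted over the list alone, with a median log2 fold change of 1.22 (camera adjusted p = 2.6e-09; adjusted p = 0.21 with an estimated correlation). Besides NR4A3 and NR4A2, the MAP kinase phosphatase DUSP4 went from 8.98 ± 0.549 to 105 ± 17.9 normalized counts (SD, n = 2), and MYC was among those that fell. Of 17 NRF2 antioxidant genes 12 fell and none rose, in both adjustments (median -0.87, adjusted p = 6.5e-07; adjusted p = 0.17 with an estimated correlation). The peroxiredoxin PRDX1 went from 8410 ± 70.3 to 2128 ± 158, the transporter ABCC4 from 1891 ± 47.8 to 614 ± 23.1, and PIR from 89.2 ± 3.13 to 17.7 ± 9.22. Of 36 interferon response genes 22 fell and 4 rose, in both adjustments (median -0.68, adjusted p = 5.9e-05; adjusted p = 0.17 with an estimated correlation). The RNA sensors OAS1 (-2.71 ± 0.38) and OAS3 (-1.40 ± 0.07) and the antiviral gene IFIT1 (-1.35 ± 0.16) fell, and IFIT2 was higher by 1.24 ± 0.19. The interferon genes that rose were 2 without CTRL_7, CTRL_8 or ONG_10. The ATF4 and interferon calls were also lost among genes with an average log2 CPM of at least 1, at adjusted p = 0.079 and 0.055.

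Lists tied to cell death and recycling moved both ways. Of 18 BCL2 family genes 5 rose and 6 fell, 6 and 6 adjusted over the list alone, with adjusted p = 0.67 for the set, a median of -0.04 and a mean of 0.29. The killer gene HRK went from 16.3 ± 0.308 to 81.1 ± 7.53 normalized counts (SD, n = 2), whereas BID (-1.04 ± 0.07) and BAX (-0.65 ± 0.10) fell on the log2 scale. In the NF-kB and inflammatory list 9 of 19 members rose and 6 fell, in both adjustments (adjusted p = 0.36). The cytokine genes IL1B (2.53 ± 0.71) and CXCL8 (1.86 ± 0.64) and the receptor gene IL2RA (2.20 ± 0.54) rose from few counts, and TNFAIP2 fell, at -1.41 ± 0.19. IL1B was not called without CTRL_7 (0.062), CTRL_8 (0.075) or ONG_9 (0.080), IL2RA without CTRL_8 (0.067) or ONG_10 (0.11), and CXCL8 without CTRL_7 (0.20), CTRL_8 (0.095) or ONG_10 (0.13). Of 22 p53 targets 6 rose and 7 fell, 9 and 8 adjusted over the list alone (adjusted p = 0.77), with the antiproliferative gene BTG2 at 1.22 ± 0.08 and the nuclease AEN at -1.02 ± 0.08. Autophagy and lysosome genes had 11 of 43 members higher and 13 lower, 12 and 15 adjusted over the list alone (adjusted p = 0.87, and 0.025 downward in fry), with the folliculin partner FNIP1 at 1.03 ± 0.06 and the protease CTSB at -0.90 ± 0.08. The median of this list was -0.12, and 0.09 with library totals. That scaling also turned the balance of counts, to 17 higher and 6 lower for autophagy, 11 and 6 for p53, and 8 and 3 for BCL2, whose median became 0.17. Without CTRL_7 the counts were 6 higher and 5 lower for autophagy, 3 higher for p53, and 4 higher and 2 lower for BCL2, with a median of 0.02. Without CTRL_8 they were 2 higher for p53, 3 higher for BCL2 and 5 higher for NF-kB.

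PRKAA2, the gene of the tagged AMPK alpha 2 subunit, was present in every library, at 409 ± 0.0944 normalized counts in Ctrl and 666 ± 5.58 without glucose (SD, n = 2). Its log2 fold change was 0.70 ± 0.08 (SE, limma, adjusted p = 4.5e-05), and reads of the introduced and the native gene are not told apart. Of 10 AMPK pathway kinase genes 2 rose and 4 fell, 3 and 5 adjusted over the list alone, with adjusted p = 0.42 for the set and a median of -0.17, which became 0.02 with scaling to library totals, where 4 rose and 1 fell. Without CTRL_7, 1 rose and 1 fell, and without CTRL_8, 1 rose and 2 fell. CAMKK2, a calcium-dependent activator of AMPK, went from 2076 ± 13.7 to 966 ± 14.8 normalized counts. STK11 (LKB1), at -0.65 ± 0.13, had adjusted p = 0.0023, and 0.071 without CTRL_7. STK11 was at 734 normalized counts in ONG_9 and 1050 in ONG_10, against 1378 ± 59.4 in Ctrl (SD, n = 2), so the size of its fall is uncertain. CAB39 (-0.27 ± 0.05), PRKAG1 (-0.26 ± 0.07) and STRADA (0.26 ± 0.08) passed the threshold with all libraries. Their adjusted p were 0.14, 0.20 and 0.17 without CTRL_7, 0.13, 0.16 and 0.38 without CTRL_8, and 0.072 for STRADA without ONG_10. PRKAA1 (-0.08 ± 0.06, adjusted p = 0.33), PRKAB1 (-0.16 ± 0.06, adjusted p = 0.077), PRKAB2 (0.17 ± 0.07, adjusted p = 0.078) and PRKAG2 (-0.19 ± 0.57, adjusted p = 0.84) did not pass. The log2 fold changes of PRKAA1 and PRKAB1 became 0.13 (adjusted p = 0.041) and 0.05 (adjusted p = 0.48) with scaling to library totals, that of PRKAG2 0.08 without ONG_10, and that of PRKAB2 kept its sign. Without ONG_9 PRKAA1 and PRKAB1 passed at 0.014 and 0.0091, and without ONG_10 PRKAB2 passed at 0.028.

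T-lineage genes moved in both directions. Of 34 such genes 11 rose and 8 fell, 11 and 9 adjusted over the list alone, with adjusted p = 0.45 for the set, a median log2 fold change of 0.07 and a mean of -0.01, while with scaling to library totals 19 rose and 6 fell and the set had adjusted p = 0.016, 1 of 4 alternatives of 21 under which it passed. The costimulatory receptor CD28 went from 666 ± 43.1 to 1232 ± 45.9 normalized counts (SD, n = 2), and the transcription factors RUNX1 and RUNX3 were higher by 0.67 ± 0.05 and 0.60 ± 0.07 (log2, SE). CD7, the early T cell marker, was at -0.92 ± 0.22, with adjusted p = 0.0077, 0.12 without CTRL_7 and 0.15 in DESeq2. Of 17 NOTCH and T-ALL oncogenes 3 rose and 8 fell, 3 and 9 adjusted over the list alone (adjusted p = 0.17). NOTCH1, the receptor often mutated in this leukaemia, went from 6348 ± 608 to 3507 ± 1104 normalized counts, its ligase target DTX1 from 1120 ± 12.8 to 628 ± 96.5 and HHEX from 332 ± 29.6 to 179 ± 4.61. TAL1 was lower by a smaller amount, at -0.42 ± 0.06. Of the NOTCH list 5 genes fell without CTRL_7 and 5 without CTRL_8, where 1 rose.

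Chromatin enzymes diverged by member. Of 35 histone and DNA methylation enzymes 18 rose and 12 fell, 19 and 12 adjusted over the list alone, with adjusted p = 0.12 for the set, and 0.011 in edgeR with TMM, 1 of 8 alternatives of 21 under which it passed. The demethylases KDM6B (1.64 ± 0.11) and KDM5B (0.97 ± 0.05) and the dioxygenase TET2 (1.10 ± 0.06) rose, and the methyltransferase DNMT3B fell, at -1.35 ± 0.09. Of 32 acetylation and BET genes 11 rose and 12 fell, 12 and 12 adjusted over the list alone (adjusted p = 0.45, median -0.01, mean 0.04, with camera's direction upward), and with scaling to library totals 15 rose and 5 fell, with a median of 0.21. This set passed under 2 of 21 alternatives. The acetyltransferase KAT6B went from 3292 ± 102 to 7294 ± 365 normalized counts (SD, n = 2), while KAT2A (-1.06 ± 0.07) and HAT1 (-0.73 ± 0.06) fell. HEXIM1, which holds the elongation kinase P-TEFb inactive, was at 0.26 ± 0.10 with adjusted p = 0.064, 0.039 in edgeR with TMM and 0.000899 without ONG_9. Of the acetylation list 5 genes fell without CTRL_7 and 7 without CTRL_8.

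Markers of other cell types were tested too. Of 8 tested B cell markers 4 fell and none rose, in both adjustments (adjusted p = 0.10, passed under 4 of 16 alternatives, with 0.0030 in fry), among them VPREB1, which went from 67.1 ± 0.314 to 8.76 ± 0.480 normalized counts (SD, n = 2), and CD79B, from 194 ± 5.11 to 81.7 ± 4.48. None of 5 myeloid markers and 3 of 5 adherent cell markers passed (1 higher, 2 lower, in both adjustments), and both sets missed the threshold at adjusted p = 0.92 and 0.87. EPCAM, an epithelial adhesion protein, was at 508 ± 37.8 in Ctrl and 403 ± 28.3 without glucose (SD, n = 2), with adjusted p = 0.020, and was not called without CTRL_7 (0.097), CTRL_8 (0.31) or ONG_10 (0.11). The myeloid median was 0.18 and the mean -0.26, with camera's direction downward. No adherent cell marker passed without CTRL_7 or ONG_10, none was lower without CTRL_8, and 1 myeloid marker was lower without ONG_10. Of the erythroid markers 3 were tested, too few for a set test, and none passed limma's threshold. The composition of the libraries is given without a test. Genes of small RNAs took 0.361% ± 0.00998 of reads in Ctrl and 0.901% ± 0.0711 without glucose, and the 10 most abundant genes 3.18% ± 0.0222 and 4.73% ± 0.0881 (SD, n = 2). ACTB led in both control libraries, with 0.431% and 0.419% of reads, and the nuclear noncoding RNA MALAT1 led in both No glucose libraries, with 0.800% and 0.751%.

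**Figure D3:**
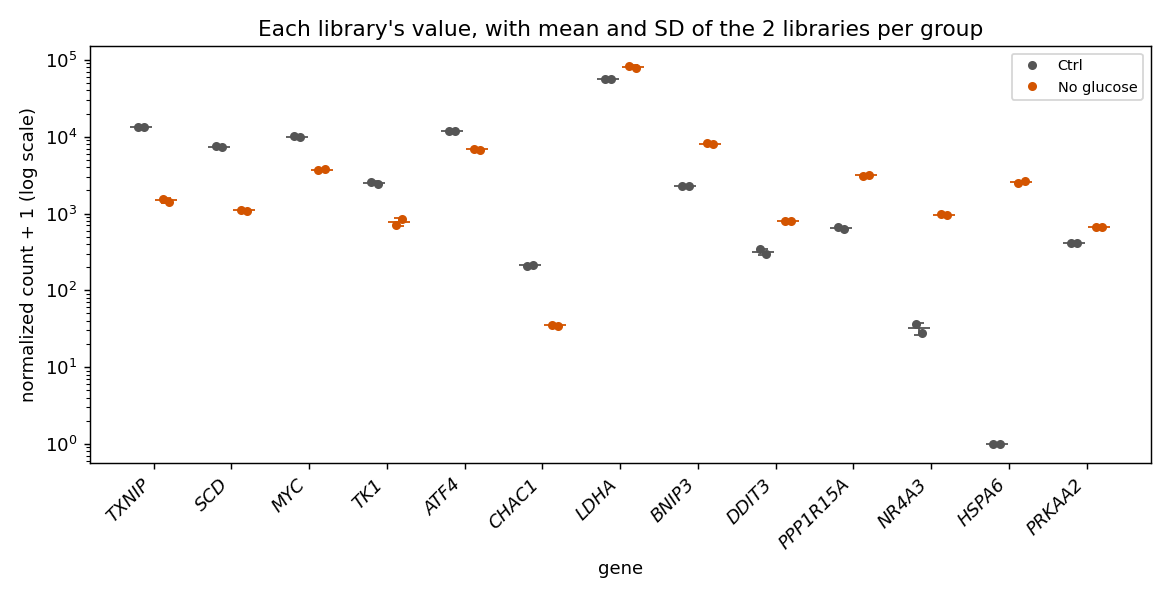
Normalized count plus 1 on a log axis for 13 genes in each library, as points, with the mean and SD of the 2 libraries of each group as a horizontal mark and bar; grey is Ctrl and orange No glucose. The groups do not overlap in any of these genes, with HSPA6 at 0 reads in Ctrl and TXNIP at 13431 against 1480 on average.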

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

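The alternatives with edgeR and TMM, limma with TMM, upper-quartile or total scaling, at least 10 reads, thinned reads and the GC and length correction were chosen only after the data were seen. Of 149 named genes, 120 kept their direction and their side of the threshold in every setting that tested them, of up to 22, and 4 turned direction in some setting. PRKAA2 stayed called in each, with log2 fold changes from 0.67 to 0.93, and the histone share difference stayed at -1.27 points. No paired analysis was possible because the columns carry no replicate number.

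With an absolute log2 fold change of at least 1 as well, 2776 genes changed, 1545 higher and 1231 lower, because that limit only removes calls. Genes higher numbered 6103 in limma with library totals, 6444 and 6244 in edgeR with upper-quartile and total scaling, and 2386 in DESeq2; the cause was not tested. After the GC and length correction 5536 genes were higher and 5267 lower, and 4 of the calls shared with the first test had the opposite sign. Leaving out 1 library in turn gave 5345 to 10559 genes changed, 2027 to 4172 higher and 3318 to 6387 lower, where the lone sample left in a group is assumed to vary like the other group. From 17 to 23 lists were called, against 18, except that camera with an estimated correlation called 0, with a smallest adjusted p of 0.166. That setting has little power with 2 libraries per group, so its lack of calls does not argue against the other settings.

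In the following, the direction of a result turned, and the cause was not tested beyond the scaling itself. With limma and library totals the log2 values were 0.0154 for AMPK pathway kinases, 0.0775 for ER chaperones, 0.0946 for autophagy and lysosome, 0.134 for PRKAA1, 0.0518 for PRKAB1 and 0.154 for ASNS. With limma and upper-quartile scaling they were -0.0534 for ER chaperones, -0.0363 for autophagy and lysosome, 0.00357 for PRKAA1 and 0.0299 for ASNS. In edgeR they were, for ER chaperones, -0.0719 (TMM), -0.0547 (RLE), 0.0959 (upper quartile) and 0.0838 (totals), and for autophagy and lysosome -0.0358, -0.0189, 0.132 and 0.120. For ASNS the same 4 gave 0.0928, 0.110, 0.260 and 0.248, and edgeR with TMM and no filter 0.00317. With edgeR upper-quartile and total scaling PRKAA1 was at 0.149 and 0.137 and PRKAB1 at 0.0656 and 0.0537.

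Among genes with an average log2 CPM of at least 1, ER chaperones were at -0.127 and autophagy and lysosome at -0.0922. After the GC and length correction ER chaperones were at -0.0895, autophagy and lysosome at 0.0427 and ASNS at 0.0939, and limma-voom gave 0.122 for ASNS. With fry ER chaperones were at -0.133 and p53 targets at 0.0468. With no filter the myeloid markers were at 0.180, and with edgeR and no filter at 0.431, where adherent cell markers were at 0.679. Where a median kept its sign, it was the set test whose direction turned, and none of these lists was called there. Autophagy and lysosome was called by fry alone, downward, at adjusted p = 0.025. Leaving out 1 library in turn gave -0.0992 to -0.0697 for autophagy and lysosome (turned without ONG_9, at -0.0697), -0.219 to 0.460 for myeloid markers and -0.438 to 0.510 for adherent cell markers (both turned without CTRL_8, at 0.460 and 0.510), -0.199 to 0.107 for ASNS (turned without CTRL_8 and, at 0.0579, without ONG_10) and -0.460 to 0.0842 for PRKAG2 (turned without ONG_10).

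Depth limits what low genes can show: 3 reads equal 1.03 normalized counts in CTRL_7 but 4.01 in CTRL_8, 4.55 in ONG_9 and 4.21 in ONG_10. With every library thinned to the shallowest, 8136 genes changed.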

Other observations

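The 5 lists below and the tests labelled so in each paragraph were chosen only after the results were seen, and the list p-values here are adjusted over these 5 lists alone. Because the members were picked with the results in view, their counts and p-values describe these lists and do not test them. Heat-inducible chaperones rose in all 12 tested members (limma, in both adjustments; median log2 fold change 1.42; camera adjusted p = 1.1e-12; adjusted p = 0.080 with an estimated correlation). DNAJB1, an HSP40 partner of HSP70, went from 2183 ± 20.8 to 18710 ± 182 normalized counts (SD, n = 2), HSPH1 from 10597 ± 48.3 to 25145 ± 1482, and DNAJA4 rose by 2.70 ± 0.07 (log2, SE). Of 27 chaperones listed here as constitutive 25 fell and 1 rose, 25 and 2 adjusted over the list alone (median -0.77, camera adjusted p = 3.0e-16, and 0.15 with an estimated correlation). The falls included TRAP1 (-1.57 ± 0.06), FKBP4 (-1.41 ± 0.06) and CCT5 (-1.29 ± 0.05), while HSP90AA1 was higher by 0.23 ± 0.05.

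Metallothioneins, which bind zinc and copper, rose in 6 of 7 tested members in both adjustments (median 1.93, adjusted p = 4.3e-05; adjusted p = 0.094 with an estimated correlation), with MT1E going from 18.1 ± 0.855 to 288 ± 15.1 normalized counts (SD, n = 2); these copies are near-identical and share reads. Of 20 negative regulators of T cell signalling 12 rose and 2 fell, 12 and 3 adjusted over the list alone (median 0.43, adjusted p = 9.2e-07; adjusted p = 0.080 with an estimated correlation), with RGS2 at 2.81 ± 0.08, DUSP10 at 2.15 ± 0.07 and CBLB at 1.83 ± 0.07. Of 26 T cell receptor segments 10 rose and 1 fell, 11 and 1 adjusted over the list alone (median 0.92, adjusted p = 7.2e-05; adjusted p = 0.080 with an estimated correlation). TRAC, the alpha chain constant segment, went from 86.5 ± 6.27 to 852 ± 36.4, while TRBC2 was level, at 5048 ± 49.5 and 5038 ± 306.

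The rise of heat-inducible chaperones could be technical, and its 3 tests were written after the result was seen. Reads shared between near-identical HSP70 genes cannot account for the part outside the HSPA family, where all 9 of the 9 tested members rose. These members were picked with the results in view, so their count does not show how far the rise extends. Correction for GC content and transcript length did not lower the median of the list, which was 1.557 after correction and 1.42 before. The correction left part of the length trend: Spearman's rho of log2 fold change with length across coding genes was 0.14 after it and 0.27 before. A handling difference between the groups, such as a warmer incubation, may produce the same picture: both (2 of 2) No glucose libraries had summed levels above both controls, 53266 and 51326 against 14775 and 14868, and a stress response to glucose loss would give the same.

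Short coding transcripts fell more than long ones (Spearman's rho 0.27 across 9941 genes), which could reflect library preparation rather than regulation. The members of the fallen lists do not carry the trend alone, since rho was 0.2579 across 9146 coding genes outside all lists. Genes with related roles may remain among these, so a joint fall of such genes is not excluded. A length trend that varies from library to library could contribute: the largest rho within a group was 0.1406 in size, against 0.238 to 0.286 between groups. A loss of short RNA fragments was tested after the result was seen, with 62 small RNA genes, whose median log2 fold change was 0.4655. These genes cannot decide the question, because a rise of their class for other reasons would hide such a loss. They are also far shorter than coding transcripts, with a median length of 137 nucleotides. No biological explanation was tested.

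Long noncoding RNAs rose relative to mRNAs, and unequal depth may explain little or some of this: in thinned reads matched for abundance the difference in median log2 fold change was 0.2404, against 0.27 unthinned and 0.15 after a GC and length correction of unthinned values. Genomic DNA in the No glucose libraries could contribute, since 498 mostly silent genes took 1.693 times the share of reads seen in Ctrl, with 180 and 192 reads in ONG_9 and ONG_10 and 552 and 129 in CTRL_7 and CTRL_8; the 95% interval of 1.49 to 1.92 covers counting error only, not the spread between libraries. Evenly spread DNA at that rate is too little to be the whole cause, since its subtraction, a test written after the result was seen, gave 0.2796, no lower than before. For transcripts running on past gene ends, the difference between strands was 0.0952 (permutation p = 0.223). This cannot decide the question, because the counting strand is not given. Reads counted without regard to strand would raise both sides alike. No biological explanation was tested.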
